A study of Homo sapiens with 4 samples.

How the data were processed

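Polyadenylated RNA of Caki-1 cells was sequenced as paired 150-base reads, 2 libraries with control hairpin RNA and 2 with hairpin RNA against TFE3. The authors deposited a table of raw read counts per Ensembl gene. Per the submitters' processing notes, Trim Galore, STAR, featureCounts and DESeq2 were used with genome build hg38, without versions. The gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Without them, levels of overlapping, antisense and near-identical genes are uncertain. A second table deposited by the authors holds their own comparison of knockdown and control for selected genes, with mean normalized signal, log2 fold changes and their standard errors, a test score, and p-values before and after adjustment; its numbers are printed here only as the authors' own.

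The table had 61533 gene identifiers. Symbols came from a gene name table for 61415 of them and from GENCODE release 29 for 105 more, and 13 had none. Coordinates are those of GENCODE release 29 on GRCh38, which may differ from the annotation behind the counts. The 46 identifiers of the second pseudoautosomal copy held 0 counts. Totals per library lay between 17270180 and 17742519 counts. The chi-square of the replicate counts divided by its degrees of freedom was 2.14 in shControl and 3.63 in shTFE3, above sampling noise, a spread that dishes or preparations of the same infection would also give. Each library was treated as a replicate.

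Groups were taken from the sample titles. The main test was edgeR 4.0.16 in R 4.3.3 on the counts as deposited: TMM factors, filterByExpr by group, a design with the arm as its only term, and the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. A threshold of 1 on the absolute log2 fold change gave the 2-fold counts. The filter left 15950 genes with 99.8% of all counts. The coefficient of variation between replicates was 4.16%, with 2 residual and 22.4 prior degrees of freedom. The standard error of a log2 fold change is its absolute value divided by the square root of the test statistic. CPM values use the TMM factors, and library means of gene lists use log2 CPM with a prior count of 2.

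A set of 31 gene lists with 776 measured genes was tested with camera of limma 3.58.1, with a preset correlation of 0.01, then with an estimated correlation and with fry. With an estimated correlation camera works with the 2 residual degrees of freedom, so hardly any list could pass. A call lost there does not by itself show that correlation between genes caused the loss. The lists covered lysosome, nutrient sensing, metabolism, stress, cell cycle, inflammation, matrix and kidney markers, and markers of other cell types. The lists, the main tests and the rule for named genes were fixed before the data were examined, while a test of direct interferon-response genes was chosen after the values were seen. The rule names TFE3, TFEB, MITF, TFEC and SLC36A1, the 10 largest rises and the 10 largest falls among called genes, and up to 4 members with the smallest p in a list. For the largest changes it asks for a mean of at least 100 counts, a symbol and no overlap of the arms in CPM. Not all genes that the rule gave are reported here. Other genes that the text names were chosen after their values were seen. Alternatives were other normalizations, filters, DESeq2 1.42.0, limma-voom, a term for the replicate number, and each library left out. A crossed pairing of the replicate numbers was added later. Both replicate blocks (the replicate term and the crossed pairing) and each fit with 1 library left out had 1 residual degree of freedom. The prior degrees of freedom were infinite for both blocks and without shControl replicate 1, and 452 without shControl replicate 2. They were 4.25 and 3.98 without shTFE3 replicates 1 and 2. With a very large prior, the variance of a gene comes almost wholly from the trend over genes. Counts from fits with such different priors are not on equal terms.

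The edgeR procedure was tested on simulated counts for 15950 genes with 50 genes changed at each size. It recovered 22 of 50 genes changed 1.25-fold, 36 at 1.5-fold, 42 at 2-fold and 50 at 4-fold, with 3 calls among 15750 unchanged genes. The simulated genes followed the dispersion trend exactly, alike in both arms, and far fewer genes changed than were called in the data. These rates therefore hold for that setting and may not carry over to the data. A scan of 7-base sites in 3' untranslated regions used GENCODE release 29 transcripts, numpy 2.4.6 and scipy 1.17.1. It covered 11099 protein-coding genes with a mean of at least 50 counts and 15830 sites, each in at least 100 genes. The chromatin immunoprecipitation that the series mentions was not analysed here.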

Results

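RNA sequencing compared Caki-1 cells, an established human renal cell carcinoma line, that carried lentiviral short hairpin RNA against TFE3 (shTFE3) or control hairpin RNA (shControl). Each arm had 2 libraries, 4 in all. The labels do not say how many hairpins were used, so libraries of an arm may differ in hairpin. TFE3 is a transcription factor of the MiT/TFE family, known for driving lysosomal genes. The series names it together with SLC36A1, a proton-coupled amino acid transporter, in the survival of kidney cancer cells without glucose. Cells were replated 24 hours after infection, puromycin was added at 1 µg/ml 12 hours later, and RNA was taken after 3 days of selection. The gene counts totalled 17316158 and 17270180 in shControl replicates 1 and 2, and 17742519 and 17631154 in shTFE3 replicates 1 and 2. A count of 3 corresponded to 0.169 to 0.174 CPM (counts scaled to the library total), the level below which a gene was not detectable, for counting error only. The labels do not say whether the replicates came from separate infections, so the p-values measure the spread between these libraries, which is technical if they did not.

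TFE3 mRNA fell to 52.9% of the control level, from 129 ± 2.04 CPM in shControl to 68.5 ± 2.25 CPM in shTFE3 (SD, n = 2). The log2 fold change of TFE3 (ENSG00000068323, chromosome X, 49028726 to 49043486, minus strand, GRCh38) was -0.92, with a standard error (SE) of 0.062 and an edgeR adjusted p of 5.6e-11. Its level was 131 and 128 CPM in the control libraries against 70.1 and 66.9 CPM in the knockdown libraries, in the direction that the labels give. SLC36A1 (ENSG00000123643, chromosome 5, 151437046 to 151492381, plus strand) fell to 64.3% of the control level, from 24.7 ± 0.35 to 15.9 ± 0.86 CPM (SD, n = 2). Its log2 fold change was -0.64 (SE 0.095, edgeR adjusted p 1.8e-05). Among the relatives of TFE3, MITF fell with a log2 fold change of -0.39 (SE 0.096, edgeR adjusted p 0.00389), while TFEB had a value of -0.21 (SE 0.14, edgeR adjusted p 0.3). TFEC had 0 and 4 counts in the control libraries and 12 and 8 in the knockdown libraries and was not tested. Of the 3 measured family members 2, TFE3 itself and MITF, fell, also when adjusted over the list alone, so the list test largely restates the knockdown (camera adjusted p 0.000399, adjusted p 0.315 with an estimated correlation). The family had a camera adjusted p of 0.0731, with 1 member down, without shTFE3 replicate 2, had 1 member up and 2 down without shControl replicate 2 (0.0296), and had 0.0751 with no filter on low counts. The fall of MITF did not pass without shTFE3 replicate 2, with a log2 fold change of -0.22 and an edgeR adjusted p of 0.221. With no filter on low counts the edgeR adjusted p was 0.303 for MITF and 0.0508 for SLC36A1.

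**Figure D1:**
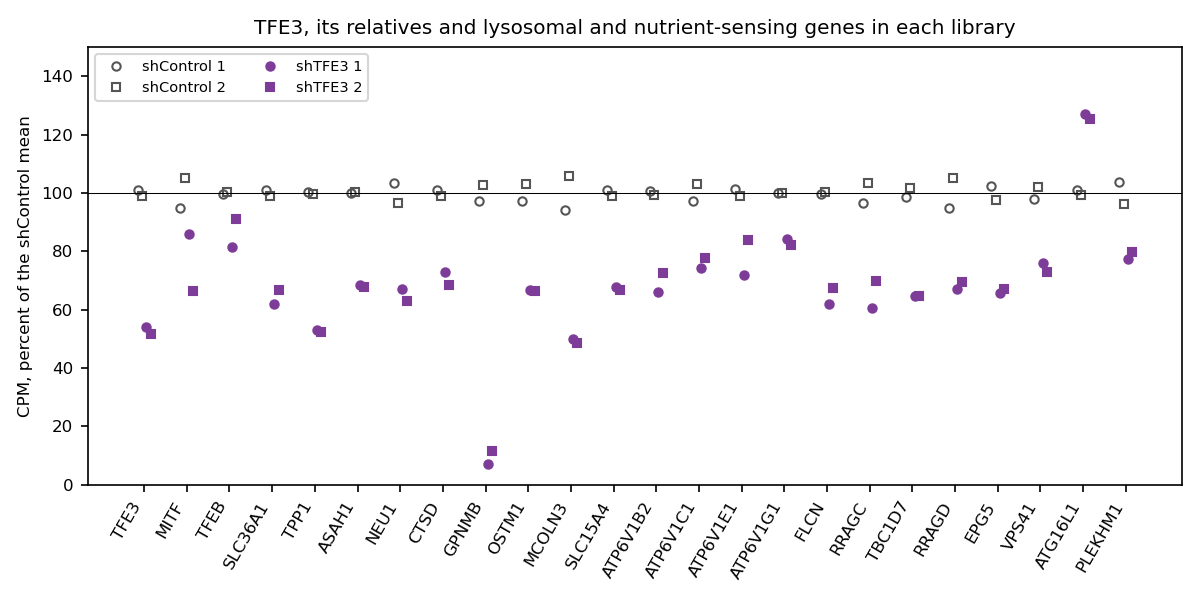
Level of TFE3, MITF, TFEB, SLC36A1 and the members with the smallest p of 5 gene lists in each library. The vertical axis gives CPM as a percent of the shControl mean, open symbols are shControl libraries, filled symbols are shTFE3 libraries, and TFE3 lies at 52.9% of the control mean over the knockdown libraries.

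Among genes with a mean of at least 100 counts, chemokine and acute-phase genes led the rises. CXCL8 rose from 7.25 ± 0.79 to 41.2 ± 1.04 CPM and CXCL6 from 63.5 ± 1.84 to 322 ± 11.2 CPM (SD, n = 2), log2 fold changes of 2.51 (SE 0.104, edgeR adjusted p 4.67e-15) and 2.34 (SE 0.061, edgeR adjusted p 4.48e-19). The next largest rises, by log2 fold change, were those of SAA2 (2.10), an acute-phase protein, TNFSF14 (1.96), CXCL1 (1.87), TNFAIP6 (1.86) and PTX3 (1.49). ZC3H12A (1.43), an RNase that degrades cytokine mRNAs, ID1 (1.43), an inhibitor of helix-loop-helix factors, and KCNAB2 (1.37) completed the 10 largest rises. SAA2 and SAA1, and CXCL1, CXCL2 and CXCL3, are similar copies, and reads shared between copies make their separate levels uncertain.

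Among genes at that level the falls were led by KCP, a secreted modulator of BMP signalling, from 48.0 ± 5.89 to 9.25 ± 0.53 CPM (SD, n = 2), a log2 fold change of -2.37 (SE 0.104, edgeR adjusted p 1.48e-14). TRPM8, a cation channel that responds to cold, fell by 2.02 on the log2 scale, the receptor tyrosine kinase FGFR2 by 1.98 and CLSTN2 by 1.95. The tight-junction gene CLDN2 fell by 1.92, the long noncoding RNA LINC02532 by 1.88, APBA1 by 1.82, ENPP5 by 1.77, SHC2 by 1.69 and the Rac activator DOCK2 by 1.67. CLSTN2 was the most abundant of these, at 437 ± 4.42 CPM in shControl and 113 ± 5.49 CPM in shTFE3 (SD, n = 2). The strand setting of the counting was not given, so reads of a gene that overlaps LINC02532 are not excluded. DOCK2 did not pass with no filter on low counts (edgeR adjusted p 0.0545).

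In all, 3709 of 15950 tested genes changed (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), of which 1650 rose and 2059 fell. Most changes were small, with a median absolute log2 fold change of 0.37, and 346 genes changed at least 2-fold, 158 up and 188 down. The 2-fold count was 99 with no filter on low counts, 165 with at least 50 counts in 2 libraries, 169 by DESeq2, 200 without shTFE3 replicate 1 and 158 without shTFE3 replicate 2. The total of changed genes was 1959 by DESeq2, 384 with no filter on low counts, 1520 without shTFE3 replicate 1 and 1043 without shTFE3 replicate 2, and the rises alone numbered 1007 without shControl replicate 1 and 1008 without shControl replicate 2. Of the 127 called genes that the naming rule gave besides TFE3 and SLC36A1, 72 lost their call with no filter, 10 by DESeq2, 9 without shControl replicate 1, 4 without shControl replicate 2, 22 without shTFE3 replicate 1 and 29 without shTFE3 replicate 2.

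**Figure D2:**
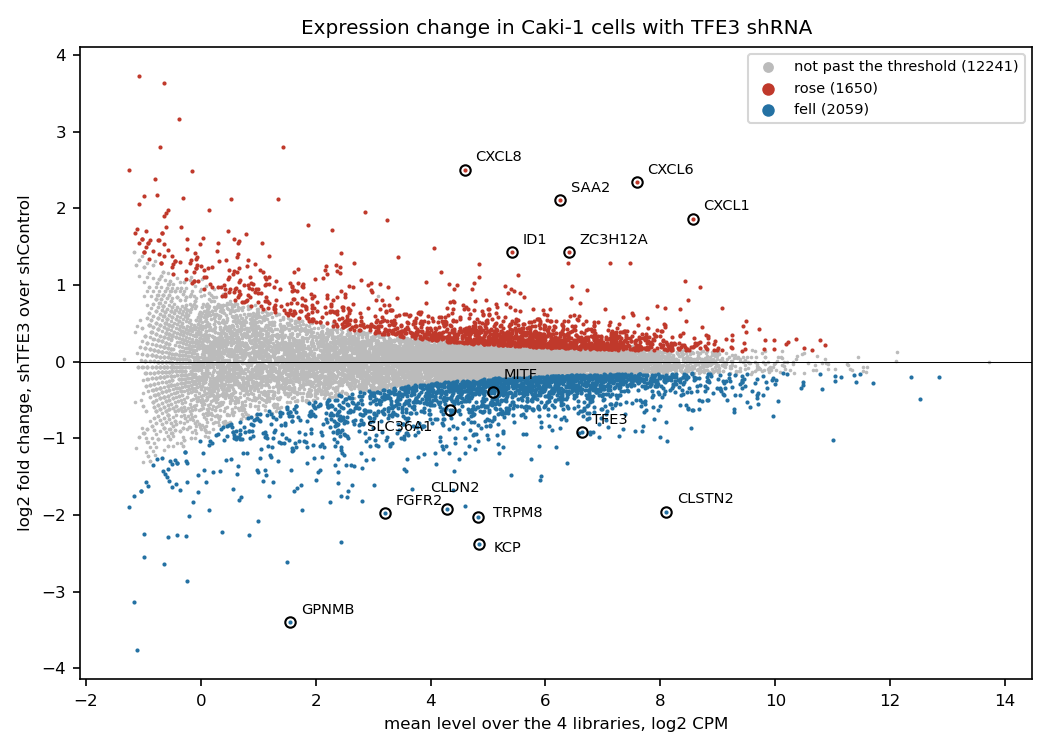
Log2 fold change of shTFE3 over shControl against the mean level over the 4 libraries in log2 CPM, 1 point per tested gene. Red points are the 1650 genes that rose, blue points the 2059 that fell, grey points genes that did not pass, and circled genes are named.

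Of 47 measured lysosomal hydrolases and cofactors, 26 fell, 1 rose and 20 did not pass (29 fell and 1 rose, adjusted over the list alone), with a median log2 fold change of -0.31. The 4 with the smallest p were TPP1, a tripeptidyl peptidase (126 to 66.5 CPM, log2 fold change -0.92), the acid ceramidase ASAH1 (-0.56), the sialidase NEU1 (-0.62) and the protease cathepsin D, CTSD (-0.50). Of 37 lysosomal membrane and transport genes, 18 fell, 4 rose and 15 did not pass (19 and 5, adjusted over the list alone), with GPNMB at -3.40 (5.37 to 0.5 CPM), OSTM1 at -0.59, the cation channel MCOLN3 at -1.02 and SLC15A4 at -0.57. Of 20 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 10 fell, 2 rose and 8 did not pass (12 and 2, adjusted over the list alone), led by ATP6V1B2 at -0.53 and ATP6V1C1 at -0.40. By camera with a preset correlation between genes of 0.01, the adjusted p was 8.7e-11 for the hydrolases, 0.000423 for the membrane genes and 0.00544 for the V-ATPase. None of these calls held with an estimated correlation, where the adjusted p was 0.315, 0.315 and 0.344. That form of the test has 2 degrees of freedom and could hardly pass any list. The estimated correlation itself was 0.053, -0.018 and 0.037. The fallen genes numbered 13 hydrolases, 8 membrane genes and 3 V-ATPase genes without shTFE3 replicate 2, and without shTFE3 replicate 1 the counts were 18, 10 and 2. Without shControl replicate 1, 4 V-ATPase genes fell. The rises among membrane genes numbered 1 without shControl replicate 1 and 0 with any other library left out, and those of the V-ATPase 1 without shControl replicate 2 and 0 with any other library left out. The hydrolase that rose did not pass without shControl replicate 1 or with either shTFE3 replicate left out. With no filter on low counts 6 hydrolases, 5 membrane genes and 0 V-ATPase genes fell, and the lists kept their camera calls.

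Markers of tumours with TFE3 fusions had 8 of 13 measured down and 2 up, the same counts when adjusted over the list alone (median log2 fold change -0.33, camera adjusted p 0.00111, adjusted p 0.315 with an estimated correlation). Those that fell included GPNMB and APOE, a lipid carrier at 2.11 CPM in shControl and 0.45 CPM in shTFE3, with FLCN and RRAGD. The 2 that rose were CTSK (161 and 213 counts in shControl, 251 and 260 in shTFE3) and SQSTM1 (29673 and 29189 against 34825 and 36806). This list is not independent of the others: GPNMB is also a membrane gene here, and FLCN, RRAGD and FNIP2, which fell too, are also mTORC1 genes. The 35 genes of mTORC1 nutrient sensing went both ways, 12 down and 6 up (12 and 7, adjusted over the list alone), and the list did not pass (camera adjusted p 0.13). FLCN (-0.63) and the Rag GTPases RRAGC (-0.62) and RRAGD (-0.55), which relay amino acid supply to mTORC1 at the lysosome, fell with TBC1D7 (-0.63). RRAGC and RRAGD did not pass with no filter on low counts (edgeR adjusted p 0.0727 and 0.0641). The 47 autophagy genes did not pass as a list (camera adjusted p 0.869), with 9 up and 7 down (10 and 7, adjusted over the list alone), a median of 0.043 (-0.006 without shControl replicate 1, 0.028 without shTFE3 replicate 2) and a mean of -0.011. Within them EPG5 (-0.59) and VPS41 (-0.43), which act in late fusion with lysosomes, fell and ATG16L1 (0.34) rose. Without shTFE3 replicate 2, autophagy had 2 up and 2 down, mTORC1 sensing 1 up and 6 down, and the fusion markers 0 up and 5 down. Without shTFE3 replicate 1, autophagy had 3 up and 2 down and mTORC1 sensing 2 up and 7 down. Without shControl replicate 1, 4 autophagy genes and 0 fusion markers rose, and without shControl replicate 2, 3 autophagy and 2 mTORC1 genes rose and 4 autophagy genes fell.

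Genes of glucose and lipid metabolism fell in part. Of 22 glycolysis genes 7 fell and 1 rose (8 and 1, adjusted over the list alone), with the enolase ENO2 at -1.67, PFKFB3 at -0.42 and PFKP at -0.39, while hexokinase HK2 rose by 0.84 (35.6 to 63.7 CPM). The list passed by camera with an adjusted p of 0.0117, and had an adjusted p of 0.469 with an estimated correlation. Of 24 cholesterol synthesis genes 8 fell, 0 rose and 16 did not pass (12 and 0, adjusted over the list alone; camera adjusted p 0.00622, adjusted p 0.334 with an estimated correlation), led by STARD4 at -0.40 and MSMO1 at -0.31. No cholesterol gene passed without shTFE3 replicate 2, STARD4 having an edgeR adjusted p of 0.145 and MSMO1 of 0.0624, while the list kept its camera call. Of 6 measured genes on the list for the glucose sensor MondoA, 4 fell, the same count when adjusted over the list alone, with KLF10 at -0.41 and TXNIP at -0.32 (camera adjusted p 0.0118, adjusted p 0.334 with an estimated correlation). The list includes MLXIP, the gene of MondoA itself, which did not pass (3969 and 3918 counts in shControl, 4184 and 4161 in shTFE3). TXNIP had an edgeR adjusted p of 0.0638 without shTFE3 replicate 2, where 1 of the 6 fell, and 2 fell without shTFE3 replicate 1. The lists of pentose phosphate and NADPH genes (2 up and 7 down of 16, 3 and 8 adjusted over the list alone, camera adjusted p 0.148, and 0.0395 with no filter on low counts), amino acid transporters (6 up and 4 down of 24, 8 and 5 adjusted over the list alone, 0.678), oxidative phosphorylation (2 up and 3 down of 46, also adjusted over the list alone, 0.545) and fatty acid synthesis (2 up and 4 down of 17, 3 and 4 adjusted over the list alone, 0.966) did not pass. Fatty acid synthesis had a median of 0.055 and a mean of -0.022, and its camera test pointed down; the median was 0.086 without shTFE3 replicate 1 and 0.031, with the test up, without shTFE3 replicate 2. Without shTFE3 replicate 1, 4 glycolysis, 5 cholesterol, 4 pentose phosphate, 2 fatty acid and 0 oxidative phosphorylation genes fell and 3 transporters rose. Without shTFE3 replicate 2, 3 pentose phosphate and 2 fatty acid genes fell, transporters had 2 up and 2 down, and oxidative phosphorylation had 0 up and 0 down and passed as a list (median -0.095, camera adjusted p 0.0169). Without shControl replicate 1, 4 pentose phosphate genes and 1 of oxidative phosphorylation fell, and 3 transporters rose without shControl replicate 2.

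Of 28 measured inflammatory cytokines and NF-kB targets, 18 rose and 3 fell (19 and 3, adjusted over the list alone), with 9 of the rises at least 2-fold. CXCL1, CXCL2, CXCL3, CXCL5, CXCL6 and CXCL8 are among these 9. The 3 that fell were TNFAIP2 (9724 and 8240 counts in shControl, 6875 and 6483 in shTFE3), ICAM1 (1517 and 1464 against 1174 and 1176) and NFKB1 (1254 and 1262 against 1088 and 1118). The median log2 fold change of the list was 0.27 and its camera adjusted p 1.08e-25, against an adjusted p of 0.207 with an estimated correlation. CXCL5 rose by 1.29 (81.2 to 198 CPM) beside CXCL6, CXCL1 and CXCL8. These neutrophil chemokine genes lie in 1 cluster on chromosome 4. In the same window CXCL2 (1.28), CXCL3 (1.25) and EREG (0.98) also rose, while MTHFD2L (log2 fold change 0.018, edgeR adjusted p 0.945) and AREG (0.059, edgeR adjusted p 0.582) did not pass; the window was chosen after the values were seen. Interferon-stimulated genes rose in part, 14 of 40 up and 5 down (15 and 5, adjusted over the list alone), with a camera adjusted p of 0.0432 and an adjusted p of 0.545 with an estimated correlation. OASL rose by 1.18 and OAS2 by 0.68, while IFITM3 fell by 0.55 and IFITM2 by 1.69. The interferon list did not pass without shControl replicate 1 (camera adjusted p 0.105) or without shTFE3 replicate 1 (0.0891), nor with the crossed replicate block (0.0503) or at least 50 counts in 2 libraries (0.0597). Without shTFE3 replicate 2, 10 inflammatory genes rose and 1 fell, and 4 interferon-stimulated genes rose; 6 of the latter rose without shTFE3 replicate 1 and 8 without shControl replicate 1, and 3 of them fell with any 1 of the 4 libraries left out. CD14, a monocyte marker, had 2 and 2 counts in shControl and 10 and 11 in shTFE3, and PTPRC, carried by all leukocytes, had at most 1 count in any library. The 3 measured markers of leukocytes, endothelium and fibroblasts did not pass (camera adjusted p 0.678).

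**Figure D3:**
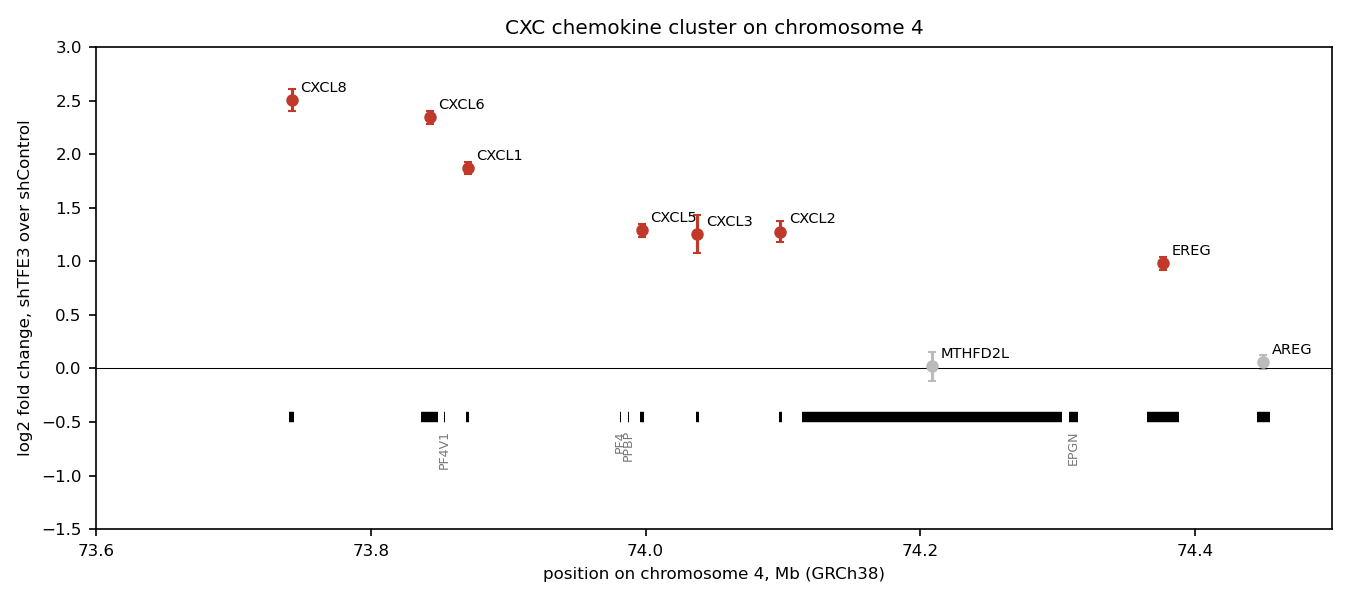
Log2 fold change with its standard error, for protein-coding genes of a window on chromosome 4 (GRCh38, megabases). Red points passed the test, grey points did not, black bars are the gene bodies, and genes with only a name had too few counts to be tested; CXCL8 at 2.51 is the highest.

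Of 40 genes of G2 and mitosis 28 rose, 0 fell and 12 did not pass (32 and 0, adjusted over the list alone), with a median log2 fold change of 0.39. CDC20 rose by 0.68 (51.6 to 82.9 CPM), TPX2 by 0.58, AURKA by 0.59 and FOXM1 by 0.54. The camera adjusted p was 1.35e-16 and the adjusted p 0.415 with an estimated correlation, which was 0.867 for this list. The mean log2 CPM of the list was 5.36 and 5.34 in shControl and 5.56 and 5.87 in shTFE3, so that the knockdown libraries lay 0.304 apart, more than the 0.204 between the nearest libraries of the arms. S phase genes had 8 down and 1 up of 40 (8 and 2, adjusted over the list alone; camera adjusted p 0.299), with means of 5.20 and 5.15 in shControl and 4.95 and 5.23 in shTFE3. Without shTFE3 replicate 2, 11 genes of G2 and mitosis rose, with a median of 0.26, and the S phase list fell (median -0.20, camera adjusted p 7.71e-06). Of the G2 and mitosis genes 0 rose with no filter on low counts, and the list had a median of 0.38 and a camera adjusted p of 2.32e-11. Without shTFE3 replicate 1 the S phase median was 0.11, with 3 genes up, 0 down and a camera adjusted p of 0.0891. Of 29 targets of p53 14 rose, 1 fell and 14 did not pass (16 and 1, adjusted over the list alone; camera adjusted p 8.27e-06, adjusted p 0.321 with an estimated correlation). They were led by CDKN1A, a cell cycle inhibitor (206 to 334 CPM, log2 fold change 0.70), and the DNA repair gene DDB2 (0.71). Without shTFE3 replicates 1 and 2, 4 and 6 p53 targets rose, and with no filter on low counts 1 rose. Of 9 measured replication-dependent histone genes 3 rose, also when adjusted over the list alone (camera adjusted p 0.103, and 0.0395 with no filter on low counts, fry adjusted p 0.04). The median was 0.209, and 0.261 without shControl replicate 1. The list holds 21 genes, and the others had too few counts to be tested. The libraries were made from polyadenylated RNA and may not measure this class of transcripts fully, so the rise is no measure of histone expression in S phase.

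Of 30 extracellular matrix and mesenchymal genes 14 fell, 3 rose and 13 did not pass (16 and 5, adjusted over the list alone), with a median of -0.30, and of -0.14 without shControl replicate 1. The collagen genes COL4A2, COL12A1 and COL4A1 fell by 0.71, 0.83 and 0.61 on the log2 scale. The camera adjusted p was 1.48e-08 and the adjusted p 0.315 with an estimated correlation. Markers of the proximal tubule, where clear cell renal carcinoma is thought to arise, had 4 of 8 measured genes down and 0 up (6 and 1, adjusted over the list alone), with PDZK1 at -0.84 and SLC17A1 at -1.15 (camera adjusted p 0.0019, adjusted p 0.315 with an estimated correlation). The list holds 26 genes, most of which had too few counts to be tested, among them LRP2 and HNF4A with 0 counts in every library. Of 27 epithelial junction and keratin genes 7 fell and 1 rose, the same counts when adjusted over the list alone, and the list did not pass (camera adjusted p 0.0801). It passed without shTFE3 replicate 1, with a camera adjusted p of 0.0183, with limma-voom (0.0377) and with no filter on low counts (0.0288). Of the epithelial genes 4 fell without shControl replicate 2, 3 without shTFE3 replicate 1 and 2 without shTFE3 replicate 2, and 1 matrix gene rose with either shTFE3 replicate left out.

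Of 27 NRF2 targets 11 rose and 6 fell (13 and 6, adjusted over the list alone; camera adjusted p 0.00561, adjusted p 0.402 with an estimated correlation), with the aldo-keto reductases AKR1C2 at 1.05 and AKR1C1 at 0.70, a pair of similar copies. With no filter on low counts the NRF2 list had a camera adjusted p of 0.135. All 13 mitochondrially encoded genes were measured and 11 fell, also when adjusted over the list alone (median -0.21, camera adjusted p 3.28e-05, adjusted p 0.402 with an estimated correlation). Mitochondrial transcripts took 4.09% and 4.08% of counts in shControl and 3.61% and 3.46% in shTFE3. Without shControl replicate 1 and without shTFE3 replicate 2, 4 of them fell, and 7 fell without shControl replicate 2. None passed with no filter on low counts, where the median was -0.22. Of 26 genes of the unfolded protein response 9 fell, 2 rose and 15 did not pass (10 and 3, adjusted over the list alone; camera adjusted p 0.0333, adjusted p 0.727 with an estimated correlation), with the chaperones CALR at -0.55 and HSP90B1 at -0.41. That list did not pass without shControl replicate 2 (camera adjusted p 0.184, 5 down) or without shTFE3 replicate 1 (0.102, 3 down), nor with at least 50 counts in 2 libraries (0.0778), and had 5 down without shTFE3 replicate 2. Of 34 genes of the ATF4 amino acid response 11 rose and 3 fell (15 and 4, adjusted over the list alone; camera adjusted p 0.0473, adjusted p 0.74 with an estimated correlation), among them SLC1A5 at 0.47 and STC2 at -0.91. The ATF4 list had a camera adjusted p of 0.158 without shControl replicate 2 (7 up) and 0.498 without shTFE3 replicate 2 (5 up). It also did not pass with the replicate block (camera adjusted p 0.0806), the crossed replicate block (0.0556) or at least 50 counts in 2 libraries (0.0698). Without shTFE3 replicate 1, 7 ATF4 genes and 7 NRF2 targets rose, and 7 NRF2 targets rose without shControl replicate 2. Cytosolic ribosomal protein genes had 3 of 54 down (1, adjusted over the list alone), a median of -0.096 (-0.03 without shTFE3 replicate 1, -0.15 without shTFE3 replicate 2), a camera adjusted p of 0.0308 and an adjusted p of 0.825 with an estimated correlation. With the crossed replicate block 10 of them were down. They did not pass without shControl replicate 1 (0.082) or without shTFE3 replicate 1 (0.495), each with 0 down, nor with at least 50 counts in 2 libraries (0.0778). By fry 9 of the 19 lists called by camera also passed. They were the MiT/TFE family, lysosomal hydrolases and membrane genes, fusion markers, cholesterol synthesis, inflammatory, MondoA, matrix and proximal tubule genes. G2 and mitosis (fry adjusted p 0.173), p53 (0.058), V-ATPase (0.058), NRF2 (0.0539), glycolysis (0.0855) and mitochondrially encoded genes (0.0855) did not pass. Nor did the interferon (0.123), unfolded protein (0.201), ribosomal (0.371) and ATF4 lists (0.424). HIF targets (6 up and 10 down of 26, also adjusted over the list alone, camera adjusted p 0.12) and immediate early and heat shock genes (6 up and 3 down of 19, 7 and 3 adjusted over the list alone, 0.102) did not pass by camera. HIF targets passed without shControl replicate 1 (0.0275), and the immediate early genes without shControl replicate 2 (0.0229) and without shTFE3 replicate 1 (0.0225, 1 down). Of the immediate early genes 2 rose without shTFE3 replicate 2. HIF targets had 5 down without shControl replicate 2, 3 up and 3 down without shTFE3 replicate 1, and 2 up and 5 down without shTFE3 replicate 2.

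**Figure D4:**
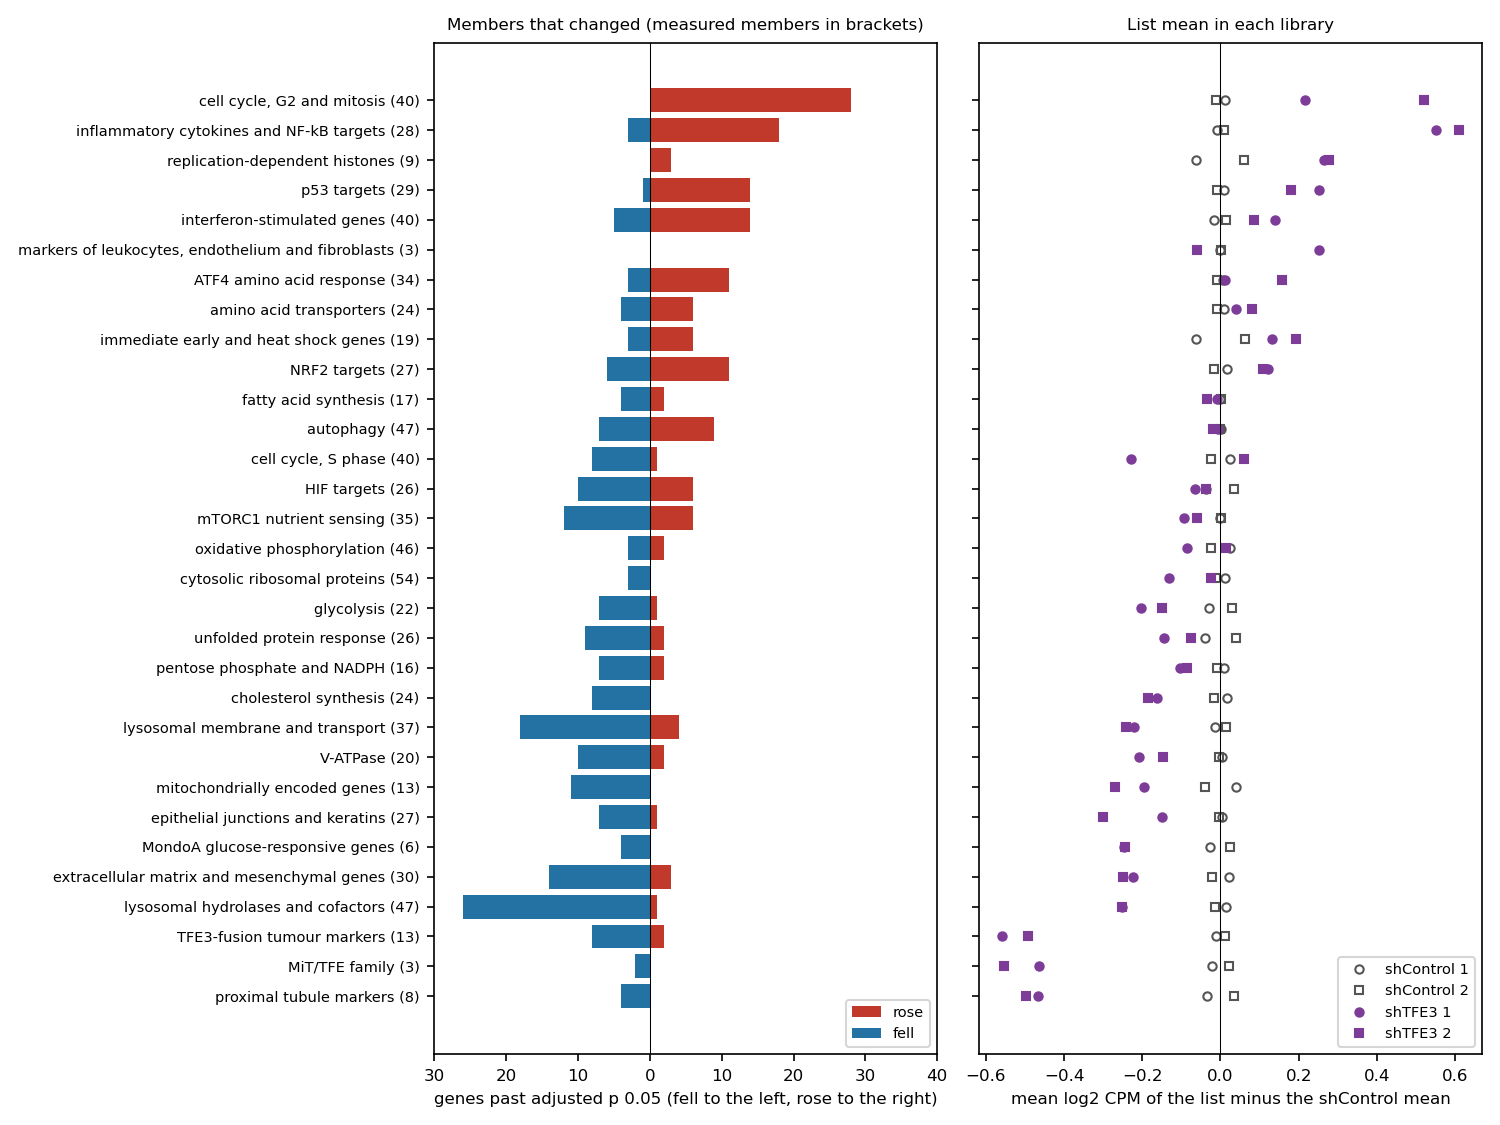
The 31 gene lists. The left panel counts members that rose (red, to the right) and fell (blue, to the left), with the number measured in brackets, and the right panel gives the mean log2 CPM of each list in each library minus the shControl mean; in the list of G2 and mitosis genes 28 of 40 rose and the shTFE3 libraries lie apart.

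The authors' deposited table of changed genes listed 546 genes, 152 up and 394 down. It held protein-coding genes with a fold change of at least 1.5 and an adjusted p of at most 0.0498. All 546 changed in the same direction in the edgeR fit, and the largest difference between its log2 fold change and that of the authors' deposited table was 0.062. Of 780 protein-coding genes that edgeR called at 1.5-fold or more, 546 (70%) stood in the authors' deposited table. DESeq2 applied to the counts called 497 protein-coding genes at that size, of which 495 stood in it. TFE3 had a log2 fold change of -0.92 and an adjusted p of 3.07e-28 in the authors' deposited table, and SLC36A1 had -0.64 and 0.00018.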

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

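The crossed pairing was chosen after the data were seen, and all other settings before. With size factors of DESeq2, upper-quartile factors, limma-voom and either replicate block, every overall count of changed genes stayed within 1.5 times the reported one. With 452 or infinite prior degrees of freedom, the blocks and the fits without a shControl replicate do not test stability. Counts within lists could move more. Ribosomal genes had 10 down with the crossed block against 3, and lysosomal membrane genes 2 up with the replicate block against 4. With no filter on low counts, 384 genes changed (104 up, 280 down; 99 at 2-fold, 31 up and 68 down), 251 of the 546 genes in the authors' deposited table were called, and SLC36A1 (-0.65) lost its call, with an edgeR adjusted p of 0.0508. The filter's absence moved edgeR's prior degrees of freedom from 22.4 to 2.09, and the 384 were all among the reported calls. With at least 50 counts in 2 libraries, which tests fewer low genes, 165 genes changed 2-fold (56 up, 109 down). DESeq2 called 1959 (752 up, 1207 down), 1958 of them also reported, and 169 at 2-fold (51 up, 118 down); the cause was not tested. Leaving out 1 library, with the lone library assumed to vary like the other arm, gave 1043 to 2514 changed genes (367 to 1008 up, 676 to 1507 down), 158 to 333 at 2-fold (55 to 146 up, 103 to 187 down), and TFE3 between -0.89 and -0.95. The lowest counts came without shTFE3 replicate 2 (1043, 158 at 2-fold) and without shTFE3 replicate 1 (1520, 200 at 2-fold), where edgeR's prior degrees of freedom were 3.98 and 4.25.

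No pairing by replicate number was seen. The correlation across genes of the deviations of same-numbered libraries was -0.029 over 15950 genes and -0.117 over 10237 genes with a mean of at least 8 CPM, and genes are not independent replicates. The replicate block gave 3558 changed genes (1568 up, 1990 down), and the crossed replicate block 4551 (2085 up, 2466 down).

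Of 31 gene lists 19 passed by camera, 0 with an estimated correlation (smallest adjusted p 0.207) and 10 by fry, which does not compare a list with other genes. The test with an estimated correlation has only 2 degrees of freedom, so its 0 alone does not show that correlation between genes undid the calls. Among lists that had passed, the estimated correlation was high for G2 and mitosis (0.867, camera p 0.228) and ribosomal genes (0.782, 0.692). It was 0.478 for the unfolded protein response (camera p 0.539), 0.433 for mitochondrially encoded genes (0.195) and 0.401 for ATF4 genes (0.573). In these lists correlation between genes also lowers the test score, apart from the degrees of freedom. For the inflammatory list the estimated correlation was -0.008, below the preset 0.01, and the camera p still went from 3.47e-27 to 0.00666. Over the settings, 191 of 209 values of these 19 lists kept their call and 18 lost it, and none changed direction. With no filter 8 inflammatory genes rose and 9 matrix genes fell, against 18 and 14, and no member passed of the lists of V-ATPase, oxidative phosphorylation, ATF4, cholesterol synthesis, S phase, G2 and mitosis, MondoA, ribosomal, epithelial, mitochondrially encoded and histone genes. In lists that had not passed, the direction of the test turned in 6 cases. Fatty acid synthesis turned up, with medians of 0.064 with at least 50 counts, 0.054 with limma-voom, 0.055 with the crossed pairing and 0.031 without shTFE3 replicate 2. Without shTFE3 replicate 1, S phase and oxidative phosphorylation turned up. With 1 library left out the medians ran from 0.031 to 0.086 for fatty acid synthesis, -0.204 to 0.11 for S phase and -0.095 to 0.000 for oxidative phosphorylation. Of 1519 values for called genes, 146 lost the call, 72 of them with no filter. ACTA2, which had not passed, turned to 0.023 without shControl replicate 1 and 0.251 without shTFE3 replicate 2, in a range from -0.418 to 0.251. The causes were not tested. At this depth 3 counts equal 0.169 to 0.174 CPM by the library total alone. In the simulation, with equal dispersion in both arms and few changed genes, 44% of 1.25-fold changes were recovered.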

Other observations

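The gene families below were chosen because members were seen to change, so their counts describe and do not test. Integrin subunits, which bind the matrix, fell in 10 of 19 measured cases and rose in 1, with ITGA3 going from 2762 ± 88.5 to 1365 ± 60.4 CPM (SD, n = 2) and ITGB4 from 61.8 ± 1.18 to 22.2 CPM. By DESeq2 9 integrins fell and 0 rose. S100 calcium-binding proteins fell in 8 of 9 cases, among them S100A6 (636 to 469 CPM) and S100A10 (282 to 187 CPM). Laminin chains split, with 6 down and 3 up of 10: LAMA5 fell from 246 to 131 CPM and LAMB3 rose from 26.3 to 52.2 CPM. Claudins had 4 down and 1 up of 10.

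Acute-phase and complement genes rose in 7 of 9 cases, with SAA1 from 103 ± 4.03 to 250.47 ± 17.9 CPM, LCN2 from 14.6 to 29.3 CPM and C3 from 1592 to 1939 CPM (n = 2), while C1R fell from 100.52 to 66.5 CPM. The directions of the family medians were the same with size factors of DESeq2 and with upper-quartile factors. Without shTFE3 replicate 2, 3 laminins and 2 claudins fell, and 1 laminin rose without shControl replicate 2 or without shTFE3 replicate 1. With no filter on low counts 4 integrins and 4 S100 genes fell, 5 acute-phase genes rose, laminins had 2 down and 1 up, and claudins 1 down and 0 up.

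The interferon test in the next paragraph was chosen after the values were seen, and the other tests before. The rise of inflammatory genes was not a trend of gene length or GC content: with that trend removed over 15462 genes, the median log2 fold change of the list was 0.264 (bootstrap 95% interval 0.187 to 0.98), against 0.271 before. This interval and those below resample the genes of a list as if independent, so they hold no spread between libraries.

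A response to double-stranded RNA, which hairpins can start, stays open for the same rise. The 14 measured genes of the direct interferon response had a median of 0.322 (interval 0.187 to 0.609), no lower than the 0.271 of the inflammatory list, and 9 of them rose and 0 fell. These genes were picked after the values were seen. The full interferon list fixed beforehand had a median of 0.15, below the 0.271, with 5 of 40 genes down. Its camera adjusted p was 0.0432 with the preset correlation and 0.545 with an estimated one. Its upper quartile was 0.347, against 1.166 for the inflammatory list, so the medians do not compare the largest rises. Neither the 14 genes nor the full list settles the point.

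The rise of G2 and mitosis genes was also not a trend of length or GC content, with a corrected median of 0.432 (interval 0.296 to 0.512) against 0.392 before. The growth state of single dishes stays open: the gap between the nearest libraries of the arms was 0.671 times the larger gap within an arm, so that 1 more dish could move the difference. For the inflammatory list and the lysosomal hydrolases the same ratio was 9.02 and 8.14.

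Lower TFE3 and matches of hairpin seeds in other transcripts are among the possible causes of the fall of many genes. Other differences between the arms were not tested. A broad seed effect was not seen: among 15830 sites of 7 bases in 3' untranslated regions, the lowest z for lower fold change was -4.16, and the lowest of 100 permutations was -5.17. With a shift of 0.2 SD planted at sites in 500 to 1500 genes, 16 of 20 sites were found, and with 0.1 SD 0 of 20. The lysosomal hydrolases kept a median of -0.328 (interval -0.381 to -0.173) after the trend of length and GC content was removed. An effect of hairpins on few transcripts stays open, since neither their sequence nor their number is given in the sources used here.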
